A study of Mus musculus with 26 samples.

How the data were processed

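Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, on granulocyte-macrophage progenitors (GMP) that had been enriched by fluorescence-activated sorting from the bone marrow of mouse offspring. GMP are the bone marrow cells from which neutrophils and monocytes arise. Offspring of mock-infected fathers are called F1R (13 libraries) and offspring of fathers that had recovered from a Candida albicans infection are called F1T (13 libraries). The labels name no litter, father, sex or batch, so p-values measure the spread between these libraries, and part of that spread may be technical. Within the sets of libraries found below, that spread was close to read sampling, so p-values need not measure a spread between animals. The number in each library's title was the other label used.

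Per the submitters' processing notes, the tools were bcl2fastq 2.20, Bowtie 1.1.1, Picard 1.134, SAMtools, MACS2 2.1.0.20140616, HOMER 4.10 and DESeq2 1.20.0, with genome build mm10. How each was set, how duplicates and mitochondrial reads were treated and whether read ends were shifted for Tn5 are not given in the sources used here. The deposited table holds 71705 peaks with 1 column per library, and all 26 columns were matched to a library by the number in its name. The deposited signal of a peak in a library is its read count divided by a size factor of that library. Multiplying each column by the size factor found from the spacing between its values gave whole reads, within 0.01 of a read, for 100% of the values in every library. DESeq2 run on those reads returned size factors that differed from the recovered ones by at most 4.47e-09%. The same table holds the authors' log2 fold changes, standard errors, test statistics (a score, per the file headers the fold change divided by its standard error), p-values and adjusted p-values for F1T over F1R, and a nearest gene, an annotation class and a distance to the transcription start site (TSS) for each peak. Of the 18422 gene symbols in the table, 18380 matched a symbol or synonym in the RefSeq table of mouse genes. Start positions are counted from 1. The nearest gene is the one with the closest TSS; where a named peak lies in an intron of another gene, that gene was looked up by the transcript in the deposited annotation.

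Before the data were examined, a count test was planned as the main test, with limma on log2 values in its place if the file held normalised values. It did, so the main test was limma 3.58.1 (lmFit, eBayes with trend and robust options) on log2(value + 1), with group as the only term, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of peaks with few reads. filterByExpr of edgeR 4.0.16 on the recovered reads kept 70641 peaks. edgeR's quasi-likelihood test with TMM scaling and DESeq2 1.42.0 on the recovered reads were run as alternatives in R 4.3.3. Tests were two-sided, and differences of single measures between groups were tested with 100000 permutations of the group labels. Principal components were computed from log2 CPM (prior count 2) of the 20000 peaks of highest mean.

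In all, 18 lists of genes were fixed before the data were examined. They held neutrophil, monocyte, stem and multipotent progenitor, erythroid and megakaryocyte, B cell, T and NK cell, dendritic cell, MHC class II, eosinophil, basophil and mast cell, inflammatory cytokine, fungal recognition, interferon, glycolysis, cholesterol, growth factor receptor, myeloid transcription factor, cell cycle and imprinted genes. A list's peaks are those whose nearest gene is a member. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), camera with an estimated correlation, and fry. The plan had camera on voom values of counts, which became an alternative. A list score of a library is the mean log2 value of the list's peaks minus the mean of all tested peaks, leaving out peaks in stretches without reads, and it was tested with 100000 permutations of the groups or 20000 within remainders. The rule for named peaks was also fixed beforehand: with fewer than 5 peaks past the threshold in a direction, the 5 of smallest unadjusted p in that direction with 1 per nearest gene; the 2 member peaks of smallest unadjusted p in each list; and the peak nearest to the TSS of Mpo, Elane, Irf8, Cebpe, Csf1r, Clec7a and Cd74. Any peak named outside this rule is said to be so.

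Several steps were added after seeing the data. Libraries were compared by the remainder of their title number on division by 4, because they clustered by it, and the remainder was used as a block. Groups were also compared with the remainder held fixed by permuting labels within each remainder. Stretches of at least 5 consecutive peaks with 0 reads where at least 100 reads were expected from the other libraries were recorded, and results were recomputed without those peaks or libraries. Runs of 4 consecutive title numbers were compared, and the title number itself was added to fits with the remainder. A planned fit had the title number centred within each group. Other alternatives were the scaling, the test, the filter, the pseudocount (0.5 and 5), 2 surrogate variables (sva 3.50.0), total reads, sex chromosomes and the chromosome Y share.

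The main test was tested on simulated data drawn from the real peaks' means and library sizes. For F1T against F1R without a block, on 70641 peaks, limma found 77 of 100 peaks changed 2-fold and 32 of 100 changed 1.5-fold, with 6 false calls. With the remainder as a block it found 82 and 50 of 100, with 5 false calls. Simulated libraries were drawn independently, and without a block all had the same mean per peak. Shifts between remainders were therefore absent from the unblocked simulation, and residuals shared by runs of title numbers from both. The rates of finding and of false calls hold for such independent libraries and may not hold for the real ones. Total reads in peaks ranged from 773171 to 5154916 per library, and the median standard error of a log2 fold change was 0.16. Floors for counts of 0 use 3 reads and cover counting error only. Correction for GC content and the search for sequence motifs needed a genome sequence and were not run. The test of peak classes among called peaks, planned for 20 or more calls, was not run, and the share near a TSS among blocked edgeR calls is given without a test.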

Results

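Accessible chromatin was profiled in sorted GMP from 26 offspring samples, 13 from mock-infected fathers (F1R) and 13 from fathers that had cleared a sublethal Candida albicans infection before mating (F1T). The study asked whether a past infection of the father changes the chromatin of myeloid progenitors in the offspring. The peak table held 71705 regions with a median width of 310 bases. By annotation, 28033 lay in introns, 25770 between genes, 11524 in promoters and 2516 in exons. Reads in peaks ranged from 773171 to 3612135 per library in F1R (median 1993301) and from 934622 to 5154916 in F1T (median 3009626). The difference in mean log2 total, 0.27, lay within the spread between libraries (permutation p = 0.313). Promoter peaks within 1 kb of a TSS held 46.3% ± 1.43 of reads in F1R and 46.1% ± 1.31 in F1T (SD, n = 13 each; permutation p = 0.776).

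The 26 libraries fell into 4 sets that followed the remainder of the title number on division by 4, and not the father's infection. Remainder 0 held 3 F1R and 4 F1T libraries, remainder 1 held 4 and 4, remainder 2 held 3 and 1, and remainder 3 held 3 and 4. The labels name GMP as the cell type of all of them. Every one of the 26 libraries had its most correlated library in the same set, against a mean of 6.09 when remainders were shuffled. Outside stretches without reads, which are described below with their libraries, 99.0% of the variance of the first principal component and 93.0% of that of the second lay between sets, and 0.97% and 0.10% between F1R and F1T. On the first 4 components of the 20000 peaks of highest mean, stretches included, the groups did not differ (smallest adjusted permutation p = 0.541). Without peaks in stretches they did not differ either (smallest adjusted permutation p = 0.255). The mean distance of a library to its group's centre was 0.27 ± 0.07 in F1R and 0.32 ± 0.18 in F1T on the log2 scale (SD, n = 13 each; permutation p = 0.371). Without peaks in stretches it was 0.26 ± 0.06 and 0.25 ± 0.05 (permutation p = 0.683), and with the remainder held fixed as well F1T was lower by the test (0.21 ± 0.04 and 0.18 ± 0.04, permutation p = 0.0244). Depth, whose median was higher in F1T, was not held fixed in these distances.

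**Figure D1:**
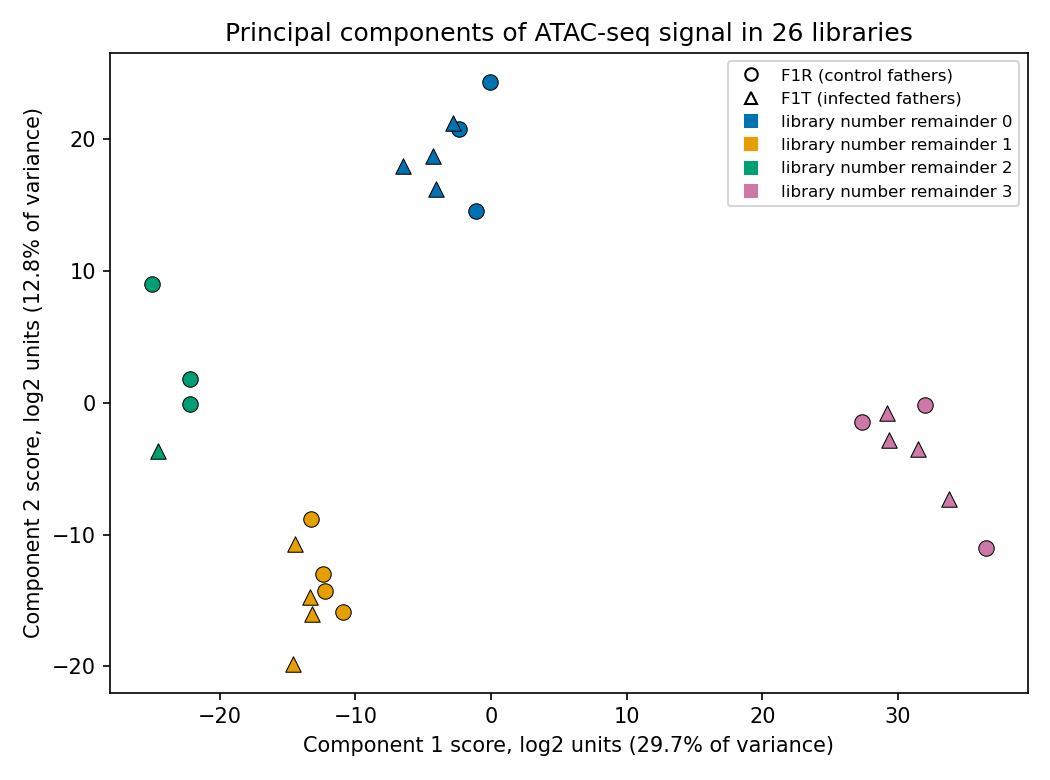
Scores of 26 libraries on the first 2 principal components of log2 CPM, leaving out peaks in stretches without reads; circles are F1R, triangles F1T, and colours the remainder of the library number. The 4 remainders form 4 separate clusters, and both groups occur in each.

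In 4 of the 26 libraries there were long stretches in which every peak had 0 reads. F1T replicate 9 had 14 such stretches on chromosomes 5, 9 and 15 with 2101 peaks over 103.4 Mb, where 83052 reads were expected from the other libraries. F1T replicate 12 had 4 on chromosomes 4 and 7 with 746 peaks, F1R replicate 4 had 3 on chromosome 13 with 546 peaks, and F1R replicate 6 had 1 on chromosome 15 with 24 peaks. A count of 0 allows at most 0.00361%, 0.00912%, 0.0227% and 0.464% of the expected reads in these libraries. Together 3393 peaks lay in a stretch of at least 1 library, and the values of these peaks in F1T or F1R carry those zeros.

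**Figure D2:**
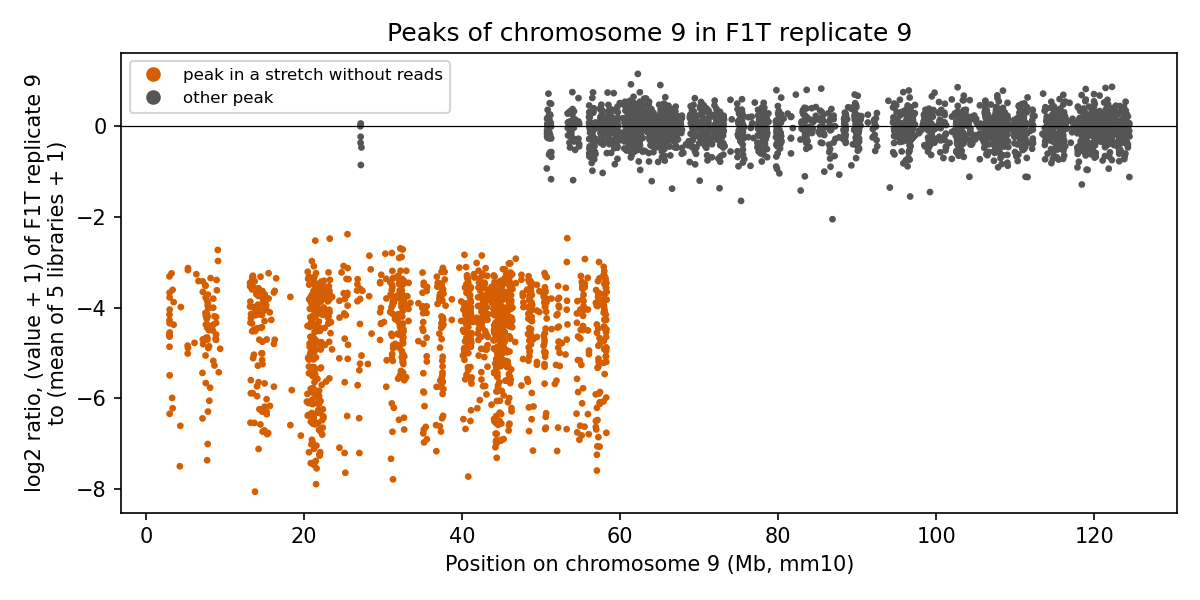
Log2 ratio of the value of each peak on chromosome 9 in F1T replicate 9 to the mean of 5 libraries of the same set without such stretches, with 1 added to both, against position in mm10. The 1315 peaks in 7 stretches without reads (orange) lie between positions 3000644 and 58313367, and the other peaks (grey) scatter around 0.

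Between offspring of infected and of control fathers, no single peak passed the threshold. limma called 0 of 70641 peaks, with a smallest adjusted p of 0.449, and 3106 peaks had an unadjusted p under 0.05, of which 1687 were higher in F1T. On the recovered reads, edgeR's quasi-likelihood test called 0 (3040 under 0.05) and DESeq2, which tested all 71705, called 0 (2461 under 0.05). The authors' deposited table also has 0 peaks with an adjusted p under 0.05, a smallest adjusted p of 0.732 and 2862 peaks with p under 0.05. With the remainder of the library number as a block, a fit added after seeing the data, limma called 1 peak, and 5907 had p under 0.05. On the 67281 peaks outside stretches without reads, the blocked fit called 2 in limma and 187 in edgeR (166 higher in F1T). On the same peaks, limma called 0 with the mean of each group and remainder as a sample. So few samples remain in that fit that its 0 decides little. With runs of 4 title numbers kept whole, 3 of 35 splits, the real split included, gave as many edgeR calls.

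The peaks of smallest p lay near genes of several functions, and none passed. A peak in an intron of Kcnj15, a potassium channel gene, on chromosome 16 at 95262664 to 95263376 had 42.5 ± 6.57 normalised reads in F1R and 56.4 ± 5.33 in F1T (log2 fold change 0.41, SE 0.08, p = 7.86e-06, adjusted p = 0.449 by limma). A peak at -23231 bases from the TSS of Hbp1, which encodes a transcriptional repressor, in an intron of the neighbouring Prkar2b, at 31973503 to 31974029 on chromosome 12 had 45.1 ± 10.4 and 60.8 ± 5.11 (log2 fold change 0.46). The other 3 of smallest p among higher values lay near Limch1 (0.74), 4921513I03Rik (0.39) and Agk (0.70). Among lower values, a peak at 22215 bases from the TSS of Etnk2, an ethanolamine kinase gene, and in an intron of Sox13, on chromosome 1 at 133385624 to 133385950 had 31.5 ± 3.59 in F1R and 22.6 ± 3.48 in F1T (log2 fold change -0.47, SE 0.09, p = 1.62e-05, adjusted p = 0.449). A peak at -4248 bases from the TSS of H2-Q8, a non-classical MHC class I gene, on chromosome 17 at 35420445 to 35420754 had 32.6 ± 4.84 and 23.1 ± 3.22 (log2 fold change -0.48). H2-Q8 belongs to a family of near-identical genes, so its reads are uncertain. The promoter of Lpgat1 (-0.31), an exon of 4931408C20Rik (-0.55) and a region near Grm4 (-0.42) completed the 5.

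The 7 myeloid genes fixed beforehand showed no difference past the threshold. At the promoter of Mpo, which encodes the neutrophil granule enzyme myeloperoxidase, the peak on chromosome 11 at 87793341 to 87793827 had 39.4 ± 21.1 normalised reads in F1R and 32.3 ± 17.2 in F1T (n = 13 each; adjusted p = 0.975 by limma). Near Elane, the gene of neutrophil elastase, the values were 21.8 ± 11.2 and 18.5 ± 9.12. The peak at the promoter of Irf8, a transcription factor of monocyte and dendritic cell development, on chromosome 8 at 120735944 to 120736497 had 55.7 ± 4.29 and 50.4 ± 6.71 (log2 fold change -0.15, SE 0.07, p = 0.0362, adjusted p = 0.975). Near Csf1r, the receptor for macrophage colony-stimulating factor, they were 13.6 ± 2.71 and 18.1 ± 4.90 (log2 fold change 0.37, p = 0.0116, adjusted p = 0.975). Cebpe, a factor of granulocyte maturation, had 25.1 ± 6.12 and 26.3 ± 5.38. Clec7a, which encodes the fungal receptor Dectin-1, had 19.4 ± 6.70 and 19.2 ± 7.25, and Cd74, the MHC class II invariant chain gene, 21.2 ± 8.47 and 20.6 ± 9.84.

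**Figure D3:**
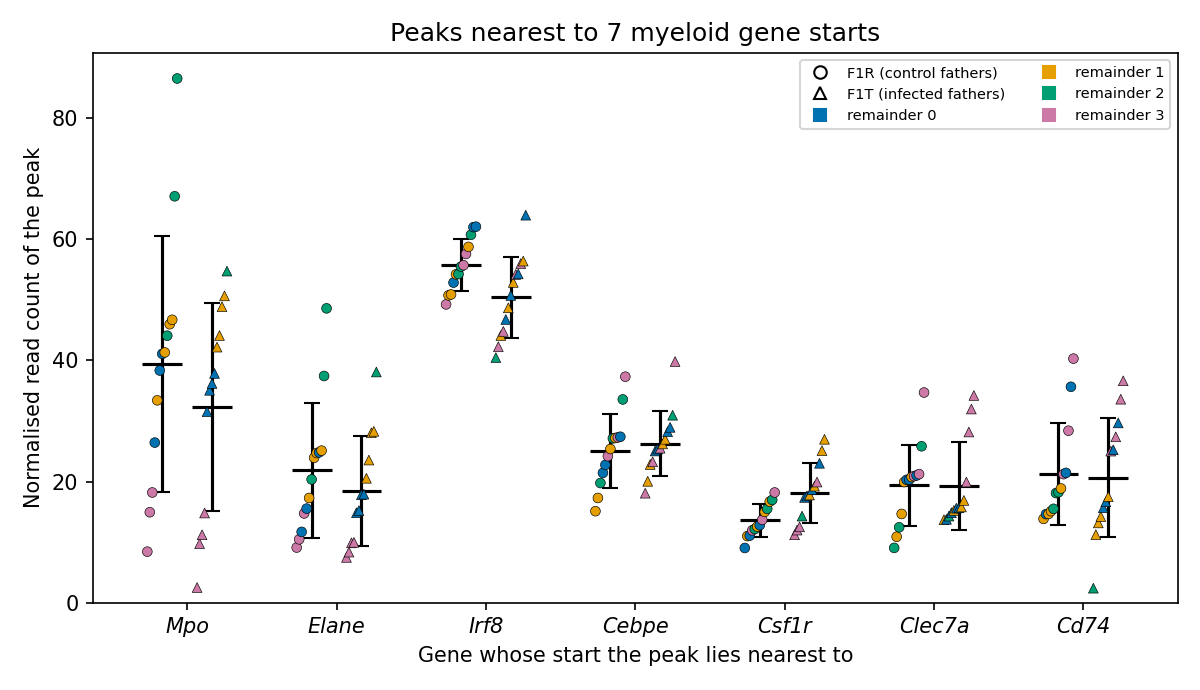
Normalised read count, per library, of the peak nearest to the start of each of 7 myeloid genes in F1R (circles) and F1T (triangles), coloured by remainder of the library number; horizontal lines and bars are the mean and SD of 13 libraries. The groups overlap at every gene, and at Mpo and Elane libraries of remainder 3 lie low in both groups.

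Peaks near stem and multipotent progenitor genes were, as a list, higher in F1T. Of its 201 tested peaks near 23 genes, 148 (73.6%) had a higher mean in F1T, against 49.7% of all tested peaks, and the median log2 fold change was 0.10 (camera, adjusted p = 0.000241). With an estimated correlation the adjusted p was 0.260, and with fry 0.399. No member passed alone, over all peaks or adjusted over the list alone (0 and 0). Of its peaks with p under 0.05, 11 were higher and 1 was lower. In an intron of Erg, an ETS factor of blood stem cells, the peak on chromosome 16 at 95452527 to 95452756 had 22.3 ± 5.35 in F1R and 29.4 ± 6.97 in F1T (log2 fold change 0.38, p = 0.00760). In an intron of Meis1, a homeobox gene of stem cells, the peak on chromosome 11 at 18885762 to 18885946 had 11.8 ± 4.13 and 15.4 ± 3.29 (0.41, p = 0.0204). By gene, 19 of 23 had a mean log2 fold change above 0, among them Procr (0.15), Angpt1 (0.14) and Kit (0.07), named after their values were seen. Robo4 (-0.37) and Esam (-0.32) were lowest, and their region is inside a stretch without reads of F1T replicate 9.

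The list score was -0.18 ± 0.10 in F1R and -0.09 ± 0.11 in F1T (permutation p = 0.0280, adjusted over 18 lists 0.504). The sets moved with it, since this score was 0.01 ± 0.06 in remainder 3 and -0.28 ± 0.05 in remainder 2, where 3 of 4 libraries are F1R. Within remainders 0, 1 and 3, F1T exceeded F1R by 0.031, 0.099 and 0.092, and by 0.073 with the remainder held fixed (permutation p = 0.00015, adjusted over 18 lists 0.0018). That permutation takes libraries within a set as independent, although runs of 4 title numbers shared residuals, as described below. With runs kept whole, 1 of 35 splits gave as large a difference, the fewest possible and not adjusted over lists. In remainder 2 the single F1T library does not allow a group value with error. With the remainder as a block, camera gave an adjusted p of 0.00849. All F1R libraries have lower title numbers than all F1T libraries, and with the remainder and the title number both in the model the list was not called (adjusted p = 0.787).

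**Figure D4:**
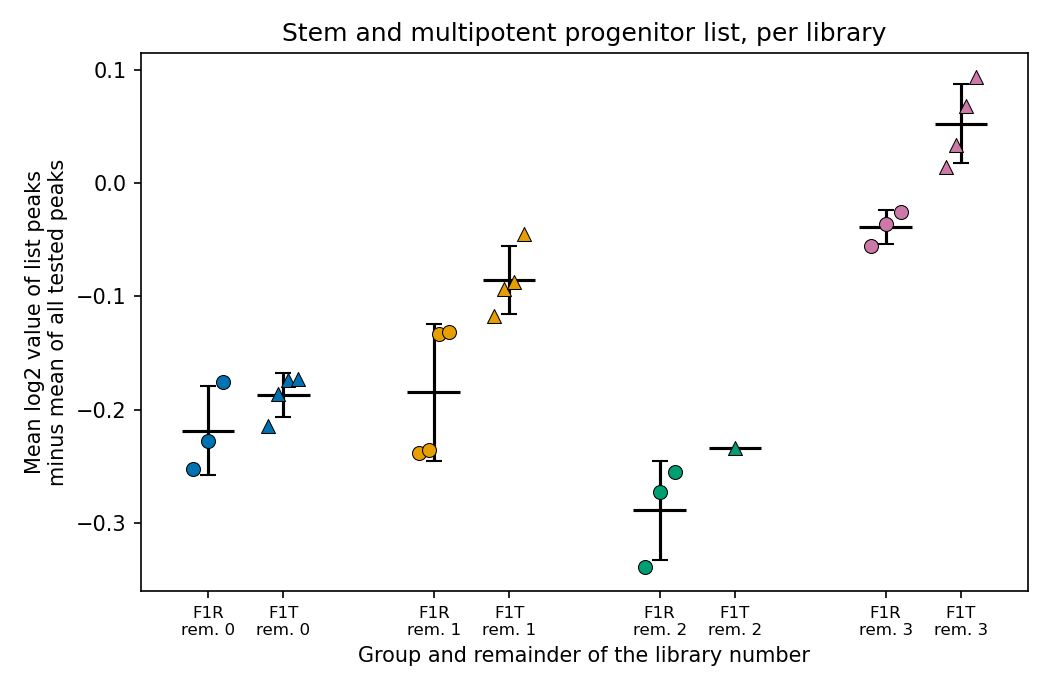
Score of the stem and multipotent progenitor list per library (mean log2 value of its peaks minus the mean of all tested peaks), by group and remainder of the library number; lines and bars are means and SDs. F1T means lie above F1R means in remainders 0, 1 and 3, and remainder 2 holds a single F1T library.

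Without a block, the lists of mature myeloid cells, myeloid transcription factors and receptors did not differ. The neutrophil and granule list (70 peaks) had a median log2 fold change of -0.066 (adjusted p = 0.386). It holds Mmp9, the gene of a granule protease (log2 fold change -0.38 for a peak at -9379 bases from the TSS, p = 0.0329), and Csf3r, the receptor for granulocyte colony-stimulating factor (0.61 in an intron, p = 0.0356). The monocyte and macrophage list (173 peaks) had a median of -0.022 (adjusted p = 0.738), and its leading peaks both lay near Ly86, at -0.56 and 0.32. Myeloid transcription factor genes (300 peaks) had a median of 0.039, with 10 peaks of p under 0.05 higher and 3 lower (adjusted p = 0.231). Their leading peaks lay near Runx1 (0.55), a factor needed for blood formation, and Fosb (0.19). Growth factor and cytokine receptor genes (204 peaks) had a median of 0.046 with 7 such peaks higher and 0 lower (adjusted p = 0.249), led by Ifngr1, an interferon gamma receptor gene (0.74), and Csf1r. With the remainder as a block, camera called both lists higher in F1T (adjusted p = 0.00785 and 0.0382), together with eosinophil, basophil and mast cell genes (adjusted p = 0.0392). The called lists share members, since Kit is in the stem and receptor lists and Gata2 in the stem and eosinophil lists. They are therefore not separate results. With an estimated correlation and without peaks in stretches, the blocked adjusted p was 0.00797 for transcription factor, 0.114 for receptor and 0.147 for eosinophil, basophil and mast cell genes, and with the title number added none of the 3 was called (0.726, 0.633 and 0.633).

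Lists tied to infection and trained immunity were not called by camera, with or without the remainder as a block. Inflammatory cytokine and NF-kB genes (154 peaks, median 0.0087, mean -0.0071) were led by Nfkb1 (0.41, p = 0.00175) and the chemokine gene Cxcl1 (0.53, p = 0.00644), and the list had an adjusted p of 0.738. Fungal recognition and pattern receptor genes (143 peaks, median -0.0087, adjusted p = 0.905) were led by a peak at -25580 bases from the TSS of Tlr2, a receptor for microbial lipoproteins, on chromosome 3 at 83867095 to 83867282. It had 15.1 ± 4.05 normalised reads in F1R and 9.42 ± 2.43 in F1T (log2 fold change -0.62, SE 0.16, p = 0.000402, adjusted p = 0.975 by limma), and the next was Plcg2 (0.22). Interferon response genes (106 peaks, median 0.021, mean -0.0014, adjusted p = 0.702) were led by the promoter of Oasl1 (0.37) and by Trim30a (0.22). Glycolysis, mTOR and HIF genes (136 peaks, median 0.014, adjusted p = 0.386) were led by 2 peaks at Hk2, a hexokinase gene (0.31 and 0.16). Cholesterol and mevalonate genes (94 peaks) had a median of 0.034 and a mean of -0.035 (adjusted p = 0.738, direction up by camera and down by fry). Their leading peaks lay near the sterol exporter gene Abcg1 (0.52, p = 0.000735) and near Sc5d (-0.78), which lies in a stretch without reads. With the remainder held fixed and peaks in stretches left out, the scores of cholesterol genes (difference 0.050, permutation p adjusted over 18 lists 0.0177) and of glycolysis genes (0.033, adjusted 0.0304) were higher in F1T. Blocked fry called both (adjusted p = 0.0134 and 0.0384), and blocked camera on those peaks did not (0.156 and 0.287), nor with the title number added (0.633 for each). With runs of 4 title numbers kept whole, 2 of 35 splits gave as large a score difference for cholesterol and 4 of 35 for glycolysis genes, so neither passed.

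**Figure D5:**
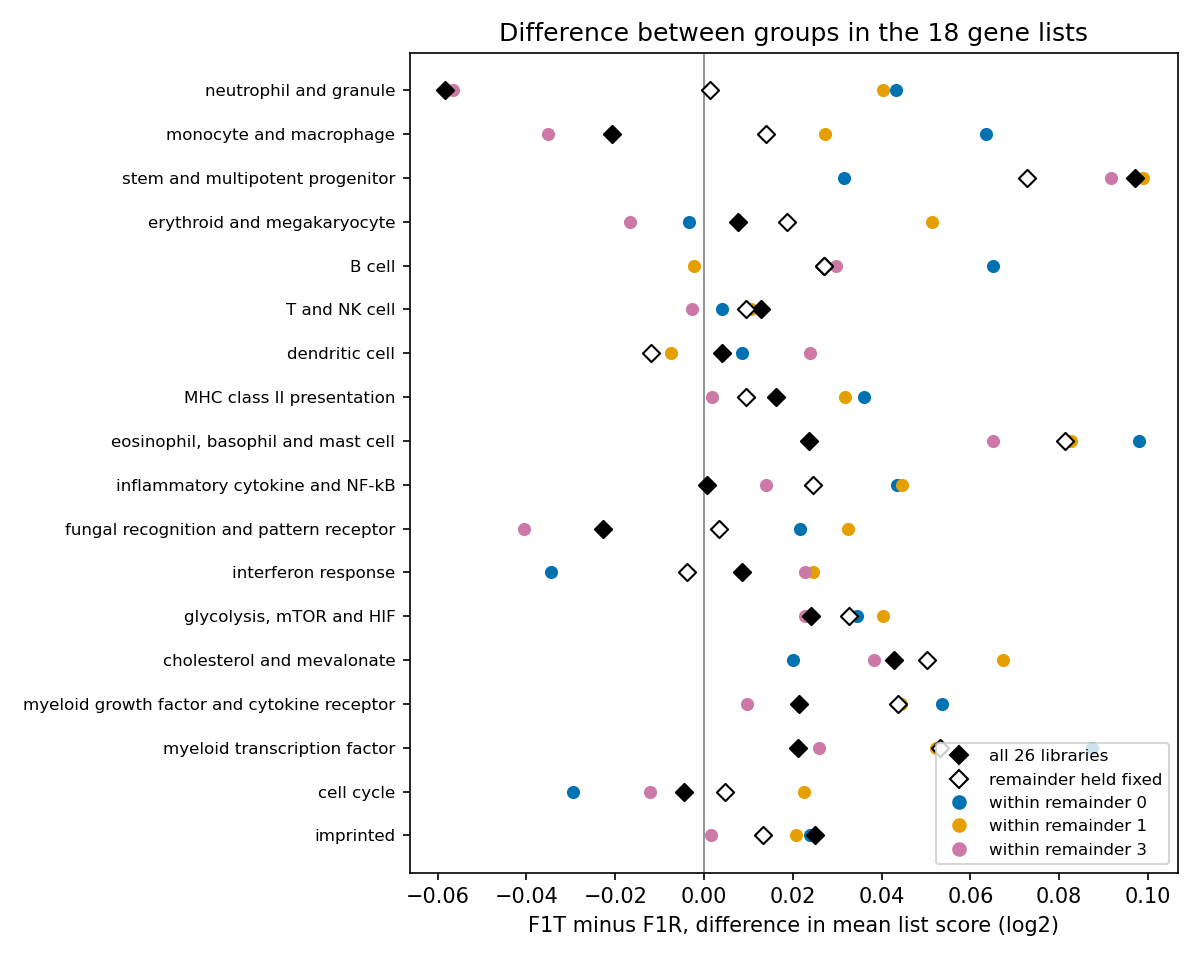
Difference in mean list score between F1T and F1R (log2, horizontal axis) for 18 gene lists (rows): filled diamonds use all 26 libraries, open diamonds hold the remainder of the library number fixed, and circles are differences within remainders 0, 1 and 3. For stem and multipotent progenitor genes the differences are 0.031, 0.099 and 0.092 within these remainders, and for neutrophil genes they lie on both sides of 0.

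Without a block, markers of other cell types and general lists did not differ at an adjusted p of 0.05. Erythroid and megakaryocyte genes (125 peaks, median -0.0013, mean 0.0046, adjusted p = 0.738) were led by Zfpm1 (-0.41) and Nfe2 (0.24). B cell genes (50 peaks, median 0.020, adjusted p = 0.702) were led by Dntt (0.20) and Pou2af1 (0.45), and T and NK cell genes (95 peaks, median -0.014, adjusted p = 0.738) by Lck (0.35) and Gata3 (0.48). Dendritic cell genes (88 peaks, median -0.012, mean 0.0044, adjusted p = 0.756) were led by Clec9a (0.37) and Tcf4 (-0.27), and MHC class II genes (63 peaks, median 0.021, adjusted p = 0.702) by the promoter of Ciita (0.29) and by H2-Oa (-0.28). Eosinophil, basophil and mast cell genes (67 peaks, median 0.018, adjusted p = 0.526) were led by Hdc (0.26) and Ccr3 (0.23). Cell cycle genes (132 peaks, median -0.031, adjusted p = 0.702) were led by Ccnd3 (0.49) and Ccne1 (0.11). Of these 132 peaks, 31 lay in stretches without reads, and without them the list score differed by -0.0045 (permutation p = 0.795). Imprinted genes (106 peaks, median 0.013, adjusted p = 0.386) were led by a peak in an intron of Airn (0.54) and one at -30892 bases from its TSS in an intron of Igf2r (0.29). Adjusted over the list alone, 0 peaks passed in any of the 18 lists without a block. With the remainder as a block, 2 neutrophil, 2 cholesterol and 1 receptor peaks passed as higher over the list alone, and 1 fungal recognition peak as lower.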

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

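The fits with the remainder of the library number, the fits without stretches, peaks or libraries, the pseudocounts of 0.5 and 5, edgeR with TMM and camera on voom values were added as alternatives after seeing the data (the last 2 had been planned as the main tests for counts); the others were planned. Among the planned covariates, the library number was centred within groups, so it could not take up a difference between them. The count of 0 called peaks stayed 0 under the other scalings, tests, filters and covariates fixed before the data were examined, on autosomes and at an adjusted p of 0.1, under edgeR with TMM, both pseudocounts, and without the peaks or the 4 libraries with stretches. It became 1 with the remainder block (5907 with p under 0.05, against 3106) and, keeping that block, 2 without peaks in stretches (Gm32511 and Usp3; 6095) and 1 without the 4 libraries (5861). Leaving out those peaks besides, so against the 2, it was 1 with runs of 4 as a random effect (5872), 1 with the library number added, and 187 in edgeR (6295). A lower residual spread accompanied the block (median SE 0.14 against 0.16). With group means per remainder as samples, on the same peaks, 0 were called, in a fit with few samples left. Peaks with p under 0.05 numbered 1665 under the stricter filter, which tested 35853 peaks, and 5495 with 2 surrogate variables, and the cause was not tested.

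The count of called lists, 1, became 0 with promoter peaks only, 0 with an estimated correlation, 0 with fry and 0 with the remainder block and library number without peaks in stretches, where number and group overlap. It became 4 with the remainder block (2 to 4 when each library was left out; 2 without F1R replicate 2, 4, 10 or 13 or F1T replicate 5, 6, 9, 10 or 11) and, keeping that block, 2 without the 4 libraries and 2 without peaks in stretches. Leaving out those peaks besides, so against that 2, it was 2 with an estimated correlation, 6 with fry and 2 with group means per remainder, and the cause was not tested. The stem list's adjusted p ranged from 3.99e-05 to 0.00218 when each library was left out, and 1 list was called except without F1R replicate 12 (2) or F1T replicate 3 (3). Of 243 pairs of an uncalled list and an alternative, 47 changed direction. The difference in spread between libraries, 0.053, became -0.0092 without peaks in stretches (permutation p = 0.683) and -0.0277 with the remainder held fixed as well (permutation p = 0.0244), which leaves out the F1T library of remainder 2; the cause was not tested. Promoter share, total reads and separation on components kept their side of the threshold. Reads on chromosome Y, used as a covariate, did not: their number for each 1e+06 reads was 369 ± 48.8 in F1R and 406 ± 57.0 in F1T (permutation p = 0.0904), and with the remainder held fixed F1T was higher by 46.4 (permutation p = 0.0308, unadjusted). GC correction and motifs could not be run without a genome sequence. Of 100 simulated peaks changed 1.5-fold, 32 were found without a block and 50 with it, for libraries drawn independently. Depth alone was not varied.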

Other observations

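The tests of the 4 sets, of the stretches without reads and of runs of numbers, the splits counted for called peaks and for peaks with p under 0.05 without a block, the splits scored over the 18 lists, and all fits with the remainder as a block, were chosen after the data were seen.

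Outside stretches without reads, the largest differences in these data lay between the sets and involved lineage genes. Libraries of remainder 3 differed from the other sets at 25733 of 67281 peaks outside stretches without reads (limma, adjusted p under 0.05), 5267 of them over 2-fold, and those of remainders 0, 1 and 2 at 8953, 10754 and 14254. The peak at the Mpo promoter had 63.1 ± 18.2 normalised reads in remainder 2 (n = 4), 44.2 ± 5.37 in remainder 1 (n = 8), 35.2 ± 4.88 in remainder 0 and 11.4 ± 5.18 in remainder 3 (n = 7 each). Cd74 went the other way, with 30.4 ± 6.75 in remainder 3 and 13.5 ± 7.55 in remainder 2. The MHC class II list to which it belongs did not follow this peak, with scores of 0.012 ± 0.055 in remainder 3 and 0.008 ± 0.052 in remainder 2. The neutrophil list score was 0.049 ± 0.090 in remainder 2 and -0.49 ± 0.06 in remainder 3. The dendritic cell score was 0.040 ± 0.030 in remainder 0 and -0.21, -0.17 and -0.17 in remainders 1, 2 and 3, and the B cell score was -0.20 ± 0.05 there against -0.55 ± 0.03 in remainder 3. The erythroid score was highest in remainder 1 (-0.018 ± 0.038) and lowest in remainder 0 (-0.19 ± 0.03).

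A difference in depth would leave no sets once depths are equal, but after thinning every library to the lowest total 26 of 26 still had their closest library in the same set. One shift in signal over background would move distal peaks of all lists together if their peaks were of like strength, which was not matched. Between remainders 3 and 2, distal peaks of the stem list and of the neutrophil list moved apart by 0.79 on the log2 scale (exact permutation p = 0.00303 over 330 splits). These sets held the extreme scores of both lists in the same data, and this p is the smallest that 330 splits give. The p-value therefore decides nothing beyond the size of the gap, and the gap does not exclude such a shift for peaks of unlike strength. Of 8 lineage lists, 7 varied between sets more than 95% of random lists of the same size, and 0 of 5 general lists did, the interferon list lying at the limit with 50 of 1000 random lists as variable. The contrast is partial, since inflammatory, fungal recognition, receptor and myeloid transcription factor lists also passed that limit (0 of 1000 random lists each) and all 5 general lists differed between sets (largest adjusted permutation p 0.0498). Random lists were also drawn peak by peak, matching neither the grouping of a list's peaks around genes nor its promoter share. The comparison therefore cannot separate lineage from these features. A candidate explanation is that the sets hold different mixtures of progenitor types, although all are labelled GMP. A library batch that moved lineage genes alone was not tested, and no label decides between them.

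The stretches without reads were weighed in the same way. Too few reads is argued against by the totals of the 4 libraries, of which the lowest was 1970625, while the library of 773171 reads had no stretch. Loss of one chromosome copy would leave the reads of the other copy, and 0 reads allow at most 0.464% of those expected in any of the 4. Reads lost in processing remain possible. The 329 peaks within 10 peaks of a stretch held 0.967 of the value in other libraries of the set. Loss of both copies allows the same value, so these flanking peaks do not decide. Such a loss would have to hold in nearly every cell, over 103.4 Mb in F1T replicate 9. In F1R replicate 4 it would span 18.3 Mb and in F1T replicate 12 15.9 Mb. For sorted cells of living mice, these lengths argue against it in those libraries. For F1R replicate 6, with 0.8 Mb, it stays open.

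The higher stem and multipotent progenitor list in F1T was the third pattern weighed. Unequal numbers of F1T and F1R libraries in the sets are argued against as the whole cause by the difference of 0.0728 (SE 0.0155) with the remainder held fixed, and a difference in depth by 0.0725 (SE 0.0162) with log2 total reads added. A steady drift along the library number stays open: the slope within groups and sets gives 0.0508 (SE 0.0237) over the mean gap of 15 numbers, and with the number in the model the difference was 0.0222 (SE 0.0276). The father's infection and the order of the libraries are confounded, so the infection remains an untested explanation.

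With the remainder as a block, limma called a single peak. A peak at -2602 bases from the TSS of Gm32511 on chromosome 9 at 71166002 to 71166347, named because it was called, had 20.2 ± 10.3 normalised reads in F1R and 32.7 ± 12.95 in F1T (n = 13 each). Its blocked log2 fold change was 0.79 (SE 0.12, adjusted p = 0.01 by limma), and within remainders 0, 1 and 3 it was 0.94, 0.47 and 0.86. With the library number added it was not called, and the 1 peak called then lay near G530011O06Rik on chromosome Y (log2 fold change 0.98, adjusted p = 0.0439). Without F1T replicate 6, the single F1T library of remainder 2, the block called 0 peaks, and without F1R replicate 5 it called 6, and 2 without F1R replicate 4 or F1T replicate 13. Of the 187 peaks that edgeR called with the block, 6.42% lay within 1 kb of a TSS against 24.8% of those tested. Members of the gene lists among them, named after their values were seen, included 2 peaks each near Angpt1 (log2 fold changes 0.65 and 0.35), Abcg1 (0.36 and 0.44) and Zeb2 (0.47 and 0.52), 1 each near Runx1 (0.59) and Zap70 (0.63), all higher in F1T, and 1 near Tlr2 that was lower (-0.68).

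Other splits of the libraries were compared with the real one, and each count of splits given here includes the real split itself. Without a block, 100 of 100 splits called as many peaks as the real 0 (highest other 1), which a real count of 0 makes certain and which therefore decides nothing. Further, 38 of 100 gave as many peaks with p under 0.05 as the real 3106 (highest other 13432), and 34 of 100 called as many lists as the real 1 (highest other 9). These splits were drawn without regard to the sets, over which the real groups are nearly even except in remainder 2. Splits uneven over the sets can take up differences between sets, which was not traced split by split. These 2 shares are thus no matched reference for the real grouping, and they do not exclude chance. Within sets and with the block, 1 of 100 gave as many peaks with p under 0.05 as the real 5907 (highest other 4324). As many lists as the real 4 came from 1 of 100 (highest other 1). As many limma calls as the real 1 came from 2 of 100 (highest other 1), and 1 of 25 gave as many edgeR calls as the real 187 (highest other 8). Chance could be excluded for each only if libraries were independent within sets, which the shared residuals of runs described below argue against. With runs of 4 consecutive numbers kept whole, 1 of 35 splits gave as many peaks with p under 0.05 (highest other 5415), but 3 of 35 gave as many edgeR calls (highest other 229), so chance cannot be excluded for the 187 when runs are the unit. Likewise 4 of the 35 called as many peaks in limma (highest other 2), and 2 of 35 called as many lists (highest other 4), so chance cannot be excluded for these counts either.

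The stem list was the 1 list called of 18, so splits scored on it alone favour the real grouping. On that score, 1 of 100 splits without a block (camera p 1.34e-05, smallest other 7.60e-05), 1 of 100 within sets with the block (0.000943, smallest other 0.00127) and 1 of 35 with runs kept whole (list score difference 0.0728, highest other 0.0661) were as extreme, and in the last the scores of eosinophil, basophil and mast cell genes and of transcription factor genes also had 1 of 35. Scored on the smallest camera p over the 18 lists, 4 of 100 splits were as extreme without a block (real 1.34e-05, smallest other 3.25e-06). Within sets with the block, 1 of 100 was (real 0.000436, for transcription factor genes, smallest other 0.00127). Neither share excludes chance, since both take libraries as independent, which the shared residuals of runs described below argue against. The splits without a block were also drawn without regard to the sets. With runs kept whole, 2 of 35 were as extreme (smallest other 0.00024), so chance cannot be excluded when runs are the unit.

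Libraries of one run of 4 consecutive numbers, which lie in different sets, resembled each other. After set and group were removed, their residuals correlated by 0.045 more than those of other libraries of the same group (permutation p = 1e-04, the smallest that the permutations give), which argues against separate animals with no shared source. One hypothesis, which was not tested, is that the libraries of a run may come from one animal or preparation. The number of independent animals per group would then be nearer 4 than 13.

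Within a set, pairs of libraries differed by a median chi-square per degree of freedom of 1.01 (0.873 to 1.32, 76 pairs). This is close to the 1 of random sampling, and 33 pairs lay under 1. The median was 0.977 for pairs of one group and 1.03 for pairs across groups, and pairs from different sets lay between 1.30 and 3.51. Blocked p-values thus rest on a spread close to read sampling, and those without a block on differences between sets as well. Reads on the mitochondrial genome ranged only from 11592 to 17478 per library (1.51-fold) while total reads ranged 6.67-fold, and the longest mitochondrial peak (11623 to 15671) held 55.9% to 84.0% as many reads as it has possible 5 prime ends on both strands.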
